A study of Homo sapiens with 18 samples.

How the data were processed

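RNA from PODO/TERT256 podocytes on hemispheres of 2 topographies, under 3 conditions, was collected with a kit for small samples, selected by poly-T and sequenced as paired reads of 150 bases from libraries that kept no strand. The notes deposited with the series name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCh38 (hg38), without saying what each did or which annotation was used. The deposited table holds raw counts as the authors made them, whole numbers for 58735 Ensembl genes in 18 libraries, with no normalization. Each library had its own column, and the groups came from the sample labels. Positions and types were added by Ensembl identifier from GENCODE 29, which held all 58735 genes. Symbols came from a current list of gene names, which had one for 41937 of these genes, and otherwise from GENCODE 29.

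Differential expression was tested with edgeR 4.0.16 in R 4.3.3. The libraries were scaled by TMM, genes were kept by filterByExpr (min.count 10, min.total.count 15), which left 16129, and 1 model with a mean for each of the 6 groups was fitted to the 18 libraries. The spread was estimated from all groups together (12 residual degrees of freedom, biological coefficient of variation 12.2%). Of 9 comparisons, 3 set fractal against smooth within a condition, 4 set a treatment against control within a topography, and 2 were interactions that test whether the treatment's effect differed between topographies. Quasi-likelihood F-tests with robust settings gave p-values, which were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Levels are CPM with TMM scaling, except that TERT, the summed macrophage markers and the ratios of markers and of gains use CPM of the unscaled totals. A fold against a group without a count was computed against a floor of 3 counts over the group, and shares of counts carry Wilson intervals at 95%.

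The 30 gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with the other genes, whereas fry asks whether the list's own genes move one way on balance. The size of the whole response was compared between topographies over genes with a mean treatment effect past the threshold. Its measure was the median of the fractal minus the smooth effect on log2 CPM (prior count 2), signed by the mean effect. An exact permutation test, two-sided, exchanged topography labels within each condition.

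The groups, comparisons, tests, thresholds, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, up to 8 protein-coding genes in each direction by fold with a mean of at least 5 CPM in the higher group and no overlap between the groups, up to 3 members of a list in each direction by adjusted p, and 12 genes chosen for podocytes and inflammation. Fewer are named in places, in rank order. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, a log2 fold threshold of 1, only the groups of the comparison, the replicate number as a block, a prior count of 0.5, and leaving out each library in turn. A run without smooth cytokines replicate 2 and fractal THP-1 replicate 3 was added after the data were seen.

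The tests were tried on simulated counts with the means of the smooth controls and, for each gene, a single spread shared by all groups. For the comparison of controls and the interaction, genes were changed in the fractal controls alone. In the real libraries the spread differed between groups, so these rates may not hold for a given comparison. With edgeR, the comparison of controls recovered 73.1% of genes changed 2-fold and 43.3% of genes changed 1.5-fold and called 5 unchanged genes. The interaction with THP-1 recovered 59.7% and 25.4% and called 7. In the comparison of topographies under cytokines, where no gene was changed, edgeR called 0 and DESeq2 called 2. A fractal response to cytokines set to 0.7 of the smooth one gave a permutation p of 0.05, which does not pass the threshold. Because the libraries kept no strand, reads of overlapping genes cannot be separated by strand, and 55 of the 131 genes whose test results are named overlap a gene on the other strand, among them ICAM1, IL6, SOD2, CDKN1A and CHRD. Reads shared by close paralogs, as for SAA1 and SAA2 or the HLA genes, leave the level of each member uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes that failed the filter were not tested, and no library was left out of the main results.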

Results

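RNA was sequenced from PODO/TERT256, a human podocyte line immortalised with telomerase. Podocytes are the epithelial cells that cover the filtration barrier of the kidney glomerulus. The cells grew on 3D hemispheres whose surface was either smooth or fractal. On each topography they were left untreated (control), given the inflammatory cytokines TNF-α and IL-6, or exposed to macrophages derived from THP-1, a human monocytic leukaemia line. This makes 6 groups of 3 libraries, 18 in all. The labels do not say whether the 3 libraries of a group came from separate cultures, so each p-value measures a spread between libraries that may be technical. A chi-square test set the differences between libraries of the same group against counting error. Its value per degree of freedom ran from 2.52 to 3.38 within controls. In the treated groups, pairs with fractal THP-1 replicate 3 gave 65.1 and 63.8. Pairs with smooth cytokines replicate 2 gave 35.9 and 36.6. The other treated pairs ran from 3.41, between fractal THP-1 replicates 1 and 2, to 12.4. Small p-values between the controls may therefore rest on a technical spread. Library totals ran from 11488204 to 21264180 counts. Levels below are means ± SD over the 3 libraries of a group, in counts per 1e6 counts (CPM), and log2 fold changes carry their SE. Intervals and floors cover counting error alone.

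Several genes that mark mature podocytes were near or below detection. NPHS1 (nephrin) had 6 counts in 2 libraries, and WT1, a transcription factor of podocytes, had 37 counts in 7 libraries. Both were too low to test. SYNPO (synaptopodin) stood at 66.6 ± 3.2 CPM and PODXL (podocalyxin) at 9.76 ± 1.3 CPM in the smooth controls. FN1, which encodes the matrix protein fibronectin, took 8.29 ± 0.04% of the counts in the fractal controls and 16.9 ± 2.2% in the fractal THP-1 libraries. TERT, the telomerase gene, had at least 1705 CPM in every library.

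Markers of monocytes and macrophages, the cells added in the THP-1 groups, differed between groups. Their summed level, SRGN left out because the podocyte line expresses it, was 8.0 ± 0.22 CPM in smooth controls and 8.70 ± 1.3 CPM in fractal controls. It was 25.3 ± 0.87 and 18 ± 1.6 CPM with cytokines. With THP-1 it was 102 ± 4.6 CPM on smooth and 49.0 ± 4.2 CPM on fractal topography. The labels state no step that would separate the cells before lysis. A pair of libraries stood apart. Fractal THP-1 replicate 3 had counts for 17934 genes, the fewest, and 0.847% of its counts on mitochondrially encoded genes (95% Wilson interval 0.842 to 0.853). The other fractal THP-1 libraries had 4.39% (interval 4.379 to 4.398) and 4.47% (4.46 to 4.48). Smooth cytokines replicate 2 had 8.09% (interval 8.08 to 8.11), against 4.23% (4.22 to 4.23) and 4.63% (4.62 to 4.63) in its companions.

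**Figure D1:**
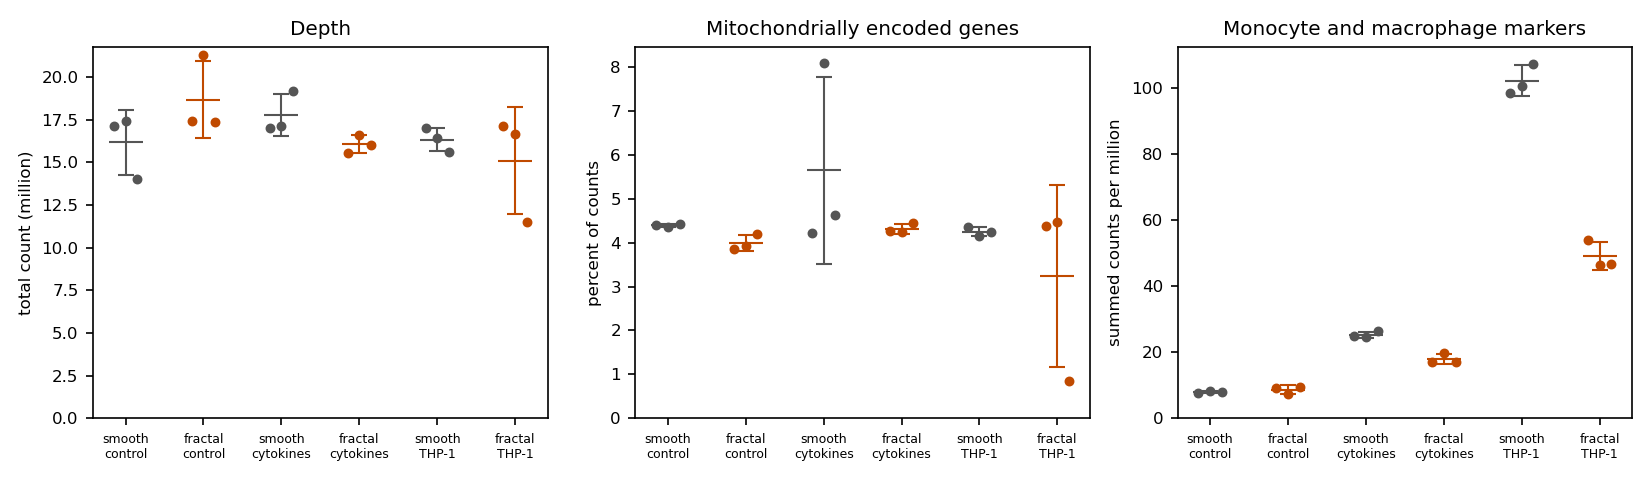
Total count (axis labelled in units of 1e6), percent of counts on mitochondrially encoded genes, and summed CPM of monocyte and macrophage markers in each of the 18 libraries. Points are libraries, bars the mean ± SD of each group of 3, with smooth in grey and fractal in orange. The marker sum is 102 CPM in the smooth THP-1 group and 49.0 CPM in the fractal THP-1 group.

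The comparison of fractal with smooth controls asks what the topography itself does to untreated cells. The genes of the 3 fibrinogen chains, clotting proteins made mainly by the liver, were higher on fractal topography. FGB (ENSG00000171564, chromosome 4, 154562956 to 154571086 in GRCh38, GENCODE 29) went from 48.2 ± 5.4 to 306 ± 2.8 CPM, a log2 fold change of 2.67 ± 0.33. FGG went from 1.14 ± 0.55 to 8.57 ± 0.47 CPM and FGA from 1.36 ± 0.53 to 5.12 ± 0.51 CPM. Genes of lipid synthesis also rose: SCD, which encodes stearoyl-CoA desaturase, by 1.09 ± 0.08, and INSIG1, a regulator of sterol synthesis, by 1.16 ± 0.14. SAMD11 (1.30 ± 0.25), PDE4B, a cyclic AMP phosphodiesterase (1.17 ± 0.18), and GDF6, a growth factor of the BMP family (1.07 ± 0.13), rose as well. The largest falls were in CHRD, which encodes the BMP antagonist chordin (-2.13 ± 0.33), the adhesion molecule L1CAM (-1.85 ± 0.34), the matrix protein gene SPON1 (-1.68 ± 0.21), the guidance factor NTN1 (-1.43 ± 0.13), the lipid transporter ABCA3 (-1.33 ± 0.19) and the membrane anchor ANK1 (-1.30 ± 0.20).

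Among the lists, 8 of 23 cholesterol synthesis genes rose and none fell (12 rose, adjusted over the list alone), among them INSIG1. Of 26 TGF-beta target genes 5 rose (11 adjusted over the list alone), among them CCN2, a matricellular protein gene (0.50 ± 0.08). Of 25 NRF2 and oxidative stress genes 2 rose (4 over the list alone), among them NQO1, a quinone reductase (0.45 ± 0.08). In the p53 target list 5 of 24 fell (13 adjusted over the list alone), with CDKN1A, the cell cycle inhibitor p21, at -0.82 ± 0.08, and BTG2 also lower. In the complement list 4 of 14 fell (6 over the list alone), with C3, the central complement protein, at -1.19 ± 0.13. In the NF-kB and TNF target list 6 of 40 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.23 (-0.21 with genes at 0 set to a floor of 3 counts over the group). Its chemokine CXCL1 fell (-0.43 ± 0.09) and PTGS2, which encodes cyclooxygenase 2, rose (0.62 ± 0.12). CXCL8, the gene of interleukin 8, went from 909 ± 13 to 702 ± 36 CPM (-0.37 ± 0.08). CCL2, a monocyte chemokine gene, had 35.2 ± 1.1 and 17.0 ± 1.3 CPM but did not pass (adjusted p = 0.133), though it did in a fit to these 6 libraries alone (2.27e-21), with DESeq2 (0.0191) and without the libraries that stood apart (0.00841).

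Rankings by fold here and below cover protein-coding genes with at least 5 CPM in the higher group. In this comparison 286 of 16129 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 105 higher and 181 lower on fractal. Each gene named from the ranking by fold had no overlap between the 3 fractal and the 3 smooth values, which chance gives for 10% of genes, and the same holds for each comparison of 2 groups below. Leaving out any 1 of smooth control replicates 1, 2 and 3 or fractal control replicates 1, 2 and 3 brought the count to between 130 and 153. A fit to these 6 libraries alone, whose spread is smaller than that of the treated groups, gave 2743 genes, 1485 higher and 1258 lower. Without the libraries that stood apart, neither of them a control, the count was 1199, with 581 higher and 618 lower. With an absolute log2 fold change of at least 1, 10 were higher and 64 lower. DESeq2 called 513, and with limma-voom CHRD missed the threshold (adjusted p = 0.099). Without smooth control replicates 1 or 2 or any of fractal control replicates 1 to 3, FGG missed the threshold (adjusted p from 0.053 to 0.098). FGA missed it without smooth control replicate 1 (0.053). CXCL8 missed it without smooth control replicates 1 or 2 or fractal control replicates 1 or 2 (0.050 to 0.11). Smaller list effects depended on the preset correlation. Of 26 immediate early genes 4 fell, or 5 adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). Of 17 heat shock genes 1 rose (adjusted p = 0.264 with an estimated correlation), and of 7 metallothionein genes, whose reads are partly shared between paralogs, 1 rose, or 2 over the list alone (adjusted p = 0.169 with an estimated correlation). Where no such p is given here and below, a list's call held with an estimated correlation too, and where 1 count is given, adjusting over the list alone gave the same.

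The cytokine groups ask how podocytes respond to an inflammatory medium. On smooth topography NF-kB and TNF target genes rose together: 30 of 40 rose and 3 fell (32 and 3 adjusted over the list alone), with a median log2 fold change of 1.15. The neutrophil chemokine CXCL6 (ENSG00000124875, chromosome 4, 73836497 to 73849064) went from 58.1 ± 4.0 to 1063 ± 204 CPM and CXCL1 from 232 ± 5.2 to 1662 ± 183 CPM. SOD2, mitochondrial superoxide dismutase, went from 107 ± 3.1 to 932 ± 114 CPM. ICAM1, a leukocyte adhesion molecule, went from 17.3 ± 1.4 to 81.6 ± 6.5 CPM, IL6 from 33.7 ± 0.97 to 165 ± 16 CPM, CXCL8 from 909 ± 13 to 2163 ± 84 CPM and CCL2 from 35.2 ± 1.1 to 114 ± 37 CPM. IL1A fell (-0.97 ± 0.24), but not in a fit to these 6 libraries alone (adjusted p = 0.069). VCAM1, another adhesion molecule, had 571 ± 4.1 and 608 ± 81 CPM and did not pass (adjusted p = 0.539).

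The largest rises on smooth topography were in KCNK12, a potassium channel gene with no count in the smooth controls and 7.92 ± 2.8 CPM with cytokines, at least 128-fold higher against a floor of 3 counts over the group. PDK4, a kinase that restrains pyruvate oxidation, rose by 7.70 ± 0.39, and the acute phase genes SAA2 and SAA1, near-identical paralogs that share reads, by 6.96 ± 0.38 and 6.41 ± 0.33. UNC13A (5.94 ± 0.68), PTGES, a prostaglandin E synthase (5.86 ± 0.28), HSD11B1, which regenerates cortisol (5.66 ± 0.65), and the transporter ABCA6 (5.53 ± 0.53) followed. BMP4 (-5.16 ± 0.44), the oxytocin receptor OXTR (-4.05 ± 0.14), PADI2, a peptidylarginine deiminase (-3.41 ± 0.28), L1CAM (-3.19 ± 0.38) and COL4A4, a collagen of the glomerular basement membrane (-3.01 ± 0.23), fell most. In other lists 9 of 15 IL-6 and STAT3 response genes rose (10 over the list alone), 7 of 14 complement genes (C3 by 4.32 ± 0.14), 16 of 29 hypoxia and glycolysis genes (ANGPTL4 by 3.17 ± 0.10), 13 of 17 MHC class I antigen presentation genes (TAPBP by 1.30 ± 0.08) and 10 of 32 type I interferon response genes (14 over the list alone). Of TGF-beta target genes 12 of 26 rose and 3 fell (13 and 4 over the list alone), with ID3 at 2.04 ± 0.11. Cell cycle genes fell in 25 of 35 cases (26 over the list alone), with TOP2A, topoisomerase II alpha, at -1.03 ± 0.09. YAP and TAZ target genes fell in 15 of 21 cases (16 over the list alone), with CCN1 at -1.05 ± 0.09, and 2 rose. Of 24 p53 target genes 12 fell, with CDKN1A at -1.10 ± 0.08, and 2 rose. In the NRF2 and oxidative stress list 8 of 25 rose and 2 fell, but that call was lost without smooth cytokines replicate 2 (adjusted p = 0.079), the library with 8.09% mitochondrial counts. Without the libraries that stood apart this list and the cell cycle list missed the threshold with an estimated correlation (adjusted p = 0.0741 and 0.0557), with calls kept under the preset correlation.

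On fractal topography the balance with cytokines was different in the NF-kB and TNF target list: 12 of 40 rose and 8 fell (the same counts adjusted over the list alone), with a median of 0.06 and a mean of 0.42. The list as a whole still passed camera upwards, also with an estimated correlation. PTGS2 (2.33 ± 0.12), SOD2 (1.97 ± 0.11), CXCL1 (1.33 ± 0.09) and IL6 (1.28 ± 0.09) rose. VCAM1 (-0.77 ± 0.09), the kinase gene RIPK2 (-0.65 ± 0.09) and LIF (-0.33 ± 0.07) fell. ICAM1 was at 22.7 ± 0.54 CPM without and 23.5 ± 1.6 CPM with cytokines, CXCL8 at 702 ± 36 and 672 ± 80 CPM, and CCL2 at 17.0 ± 1.3 and 17.9 ± 4.7 CPM. These 3 did not pass the test.

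Other responses on fractal topography were large. PDK4 rose by 8.24 ± 0.42, the chemokine CXCL12 by 7.41 ± 0.35, SAA1 by 6.24 ± 0.44, SULF1, a heparan sulfate sulfatase, by 6.20 ± 0.31, the synaptic vesicle gene SNAP25 by 5.54 ± 0.50 and the phosphodiesterase PDE1A by 5.13 ± 0.31. SAA2 and HSD11B1 rose from 1 and 2 counts over the control group to 6.67 ± 2.7 and 6.22 ± 1.6 CPM. The monocarboxylate transporter SLC16A12 (-2.86 ± 0.40), DCDC2 (-2.85 ± 0.23), OXTR (-2.66 ± 0.13), the cadherin CDH5 (-2.65 ± 0.31), PADI2 (-2.49 ± 0.25) and SCD (-1.94 ± 0.08) fell. Rises covered 13 of 15 IL-6 and STAT3 response genes, 8 of 14 complement genes (C1R by 3.85 ± 0.13), 21 of 29 hypoxia and glycolysis genes, 17 of 26 TGF-beta target genes (ID1 by 1.38 ± 0.10), 15 of 27 fibrillar collagen and stromal matrix genes (DCN, decorin, by 4.09 ± 0.16) and 11 of 26 immediate early genes (FOSB by 3.03 ± 0.20). Those lists held 0, 1, 0, 3, 2 and 4 genes that fell. For the immediate early list the call held without the libraries that stood apart, but not with an estimated correlation as well (adjusted p = 0.0653). Adjusted over the list alone, 23 hypoxia and glycolysis genes and 15 immediate early genes rose and 1 and 5 fell, and 1 IL-6 and STAT3 response gene fell. Cell cycle genes fell in 32 of 35 cases (34 over the list alone), YAP and TAZ target genes in 14 of 21 (16 over the list alone), with 2 rising, and cholesterol synthesis genes in 14 of 23. By edgeR's quasi-likelihood test, 4144 genes changed with cytokines on smooth (2136 higher, 2008 lower) and 4167 on fractal (2089 higher, 2078 lower). With RLE factors the lower genes were more numerous (2083 to 2103 and 2033 to 2154), and with upper-quartile factors the higher ones (2135 to 2016 and 2295 to 1854).

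Between the topographies under cytokines, NF-kB and TNF target genes were lower on fractal: 31 of 40 fell and none rose (38 and none adjusted over the list alone), with a median of -1.07. CXCL6 stood at 116 ± 22 CPM against 1063 ± 204 on smooth (-3.19 ± 0.14) and CXCL8 at 672 ± 80 against 2163 ± 84 (-1.69 ± 0.08). CCL2 (-2.67 ± 0.31), ICAM1 (-1.79 ± 0.09), IL6 (-1.47 ± 0.09), SOD2 (-1.40 ± 0.11) and VCAM1 (-0.69 ± 0.09) were also lower. CSF2, the gene of the growth factor GM-CSF, had the largest fall among genes with at least 5 CPM in the higher group (7.38 ± 4.0 against 0.61 ± 0.25 CPM, -3.57 ± 0.36). IQCD (-3.17 ± 0.13), the serine protease gene TMPRSS2 (-3.14 ± 0.36), TTC29 (-2.93 ± 0.29), UNC13A (-2.68 ± 0.50) and SERPINB2, an inhibitor of plasminogen activators (-2.49 ± 0.17), fell as well. FGG (2.94 ± 0.55), FGA (2.89 ± 0.35), PTPRN (2.77 ± 0.50), FGB (2.08 ± 0.32), the cGMP-dependent kinase gene PRKG2 (1.90 ± 0.31), SAMD11 (1.66 ± 0.23) and SCG2, a secretory granule protein gene (1.63 ± 0.34), were higher. TNF, with 0.56 ± 0.28 CPM on smooth and 1 count over the fractal group, passed (adjusted p = 0.0123) but missed the threshold without fractal cytokines replicate 1 (0.0727) or 3 (0.0686).

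**Figure D2:**
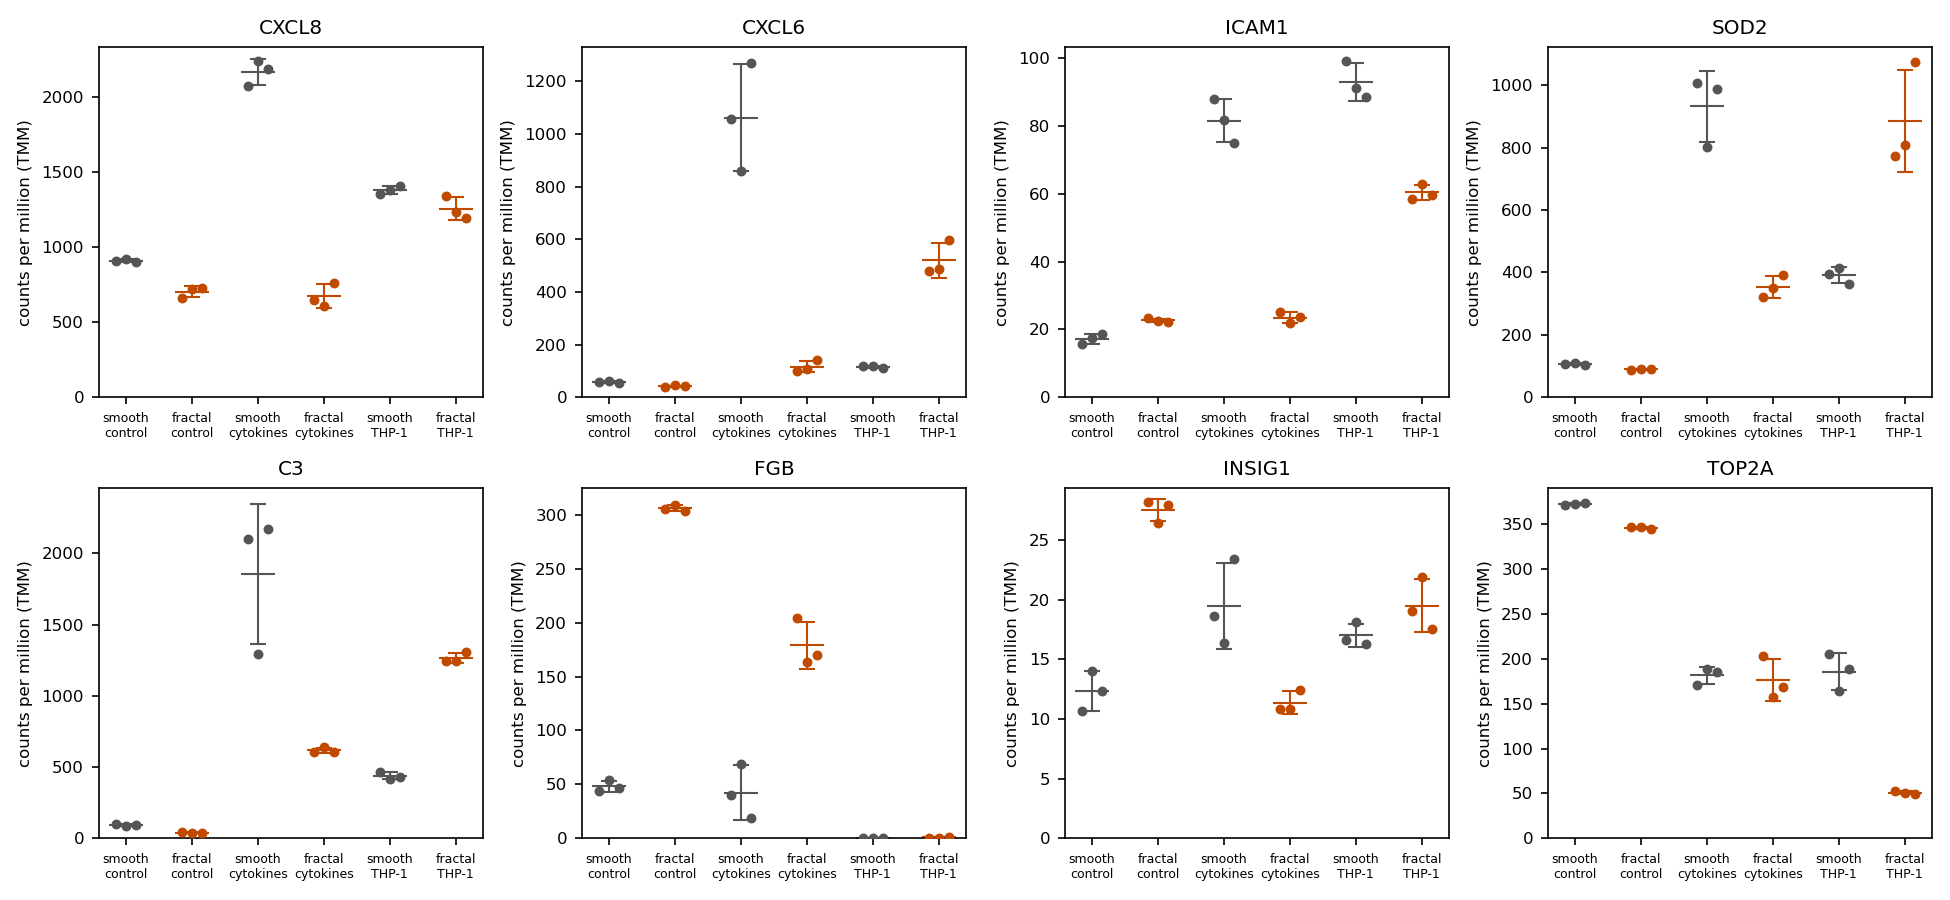
CPM of 8 genes in each of the 18 libraries, with TMM scaling and linear axes from 0. Points are libraries and bars the mean ± SD of each group of 3, with smooth in grey and fractal in orange. CXCL6 is at 1063 CPM on smooth and 116 CPM on fractal topography with cytokines, and at 117 and 520 CPM with THP-1.

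In the MHC class I antigen presentation list 8 of 17 genes were lower on fractal under cytokines (10 over the list alone), with TAPBP at -0.83 ± 0.08 and HLA-B at -0.76 ± 0.10, and 4 of 32 type I interferon response genes were lower (6 over the list alone), with MX1 at -2.11 ± 0.36. Complement genes went both ways: C1QTNF1 (-1.59 ± 0.11) and C3 (-1.59 ± 0.12) were among 5 that fell, 1 rose, and the median was -0.04 while the mean was 0.05 and the list test pointed down. Fibrillar collagen and stromal matrix genes were higher in 8 of 27 cases and lower in 1 (13 and 4 over the list alone), with TGFBI (0.73 ± 0.07), COL6A3 (0.89 ± 0.10) and the proteoglycan BGN (1.60 ± 0.19) up and DCN (-0.84 ± 0.13) down. Of 10 mesangial and smooth muscle markers 3 were higher (4 over the list alone), among them PDGFRB (0.82 ± 0.12), and of 26 TGF-beta target genes 8 were higher and 2 lower. The test called 719 genes, 277 higher and 442 lower on fractal. Without fractal cytokines replicate 1 it called 472. In a fit to these 6 libraries alone FGG and FGB missed the threshold (adjusted p = 0.17 and 0.18). Without smooth cytokines replicate 2 and fractal THP-1 replicate 3, the libraries that stood apart, 1569 genes were called and 34 of the 40 NF-kB and TNF target genes were lower. In that run the collagen and TGF-beta lists, with medians of 0.26 and 0.11, kept their calls with the preset correlation (adjusted p = 0.000108 and 0.000671) and missed the threshold with an estimated correlation (adjusted p = 0.20 and 0.082).

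The interaction of topography and cytokines tests whether the response itself differed. NF-kB and TNF target genes responded less on fractal: 22 of 40 had a smaller rise or a larger fall and none the opposite (30 and none adjusted over the list alone), with a median difference of -0.85. ICAM1 (-2.19 ± 0.13), CXCL6 (-2.73 ± 0.18), CXCL5 (-2.33 ± 0.19), CXCL1 (-1.51 ± 0.12), CXCL8 (-1.31 ± 0.11), SOD2 (-1.15 ± 0.15), IL6 (-1.01 ± 0.13) and VCAM1 (-0.86 ± 0.13) were among them. CSF2 (-2.56 ± 0.50), the prostaglandin synthase gene PTGES (-2.25 ± 0.42), the interleukin 7 receptor gene IL7R (-2.26 ± 0.43), CD83 (-2.18 ± 0.40) and SULT1B1, a sulfotransferase gene (-3.09 ± 0.67), also responded less. For CCL2 the difference was -1.62 ± 0.43 (adjusted p = 0.067), and it passed without smooth cytokines replicate 2 (0.045), with DESeq2 (0.0058) and in a fit to these 12 libraries alone (0.032). Cholesterol synthesis genes differed in the same direction in 6 of 23 cases (12 over the list alone), with INSIG1 at -1.94 ± 0.20. In the MHC class I list 3 of 17 differed (8 over the list alone), with TAPBP at -0.93 ± 0.11, and in the type I interferon list 1 of 32 (3 over the list alone), IFIH1 at -1.27 ± 0.28. The interferon list kept its call without the libraries that stood apart (adjusted p = 0.00766), but not with an estimated correlation as well (adjusted p = 0.0751).

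More positive responses on fractal were seen for CXCL12 (3.21 ± 0.64), PAPPA2 (3.12 ± 0.62), SULF1 (2.92 ± 0.46), DRAXIN (2.54 ± 0.35), INHBE (2.49 ± 0.48) and COL4A4 (2.34 ± 0.31), the last because its fall was smaller. In the immediate early list 5 of 26 genes had a more positive response (6 over the list alone), led by the transcription factors FOS (2.10 ± 0.32), KLF4 (1.70 ± 0.29) and FOSB (1.51 ± 0.27), and in the p53 target list 3 of 24 (7 over the list alone), with CDKN1A at 1.28 ± 0.11. The quasi-likelihood test called 436 genes, 206 with a more positive and 230 with a more negative difference, or 232 and 202 under upper-quartile scaling. The count was 274 without smooth control replicate 1, 283 without smooth control replicate 2, 270 without fractal control replicate 2 and 275 without fractal control replicate 3, and 1472 without the libraries that stood apart. DESeq2 called 688 and a fit to these 12 libraries alone 984. With limma-voom CSF2, PTGES and CXCL12 missed the threshold (adjusted p = 0.060, 0.062 and 0.074). Over the 6041 genes that responded to cytokines on average, no difference in the size of the response passed the test. The median signed difference was -0.00080 (exact permutation test, two-sided, 400 relabellings, p = 0.985), with median responses of 0.463 on smooth and 0.456 on fractal. The difference was positive without fractal control replicates 1, 2 or 3 (0.00710, 0.00697 and 0.00399), smooth cytokines replicate 1 (0.00938) or fractal cytokines replicates 1 or 3 (0.0244 and 0.0153).

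**Figure D3:**
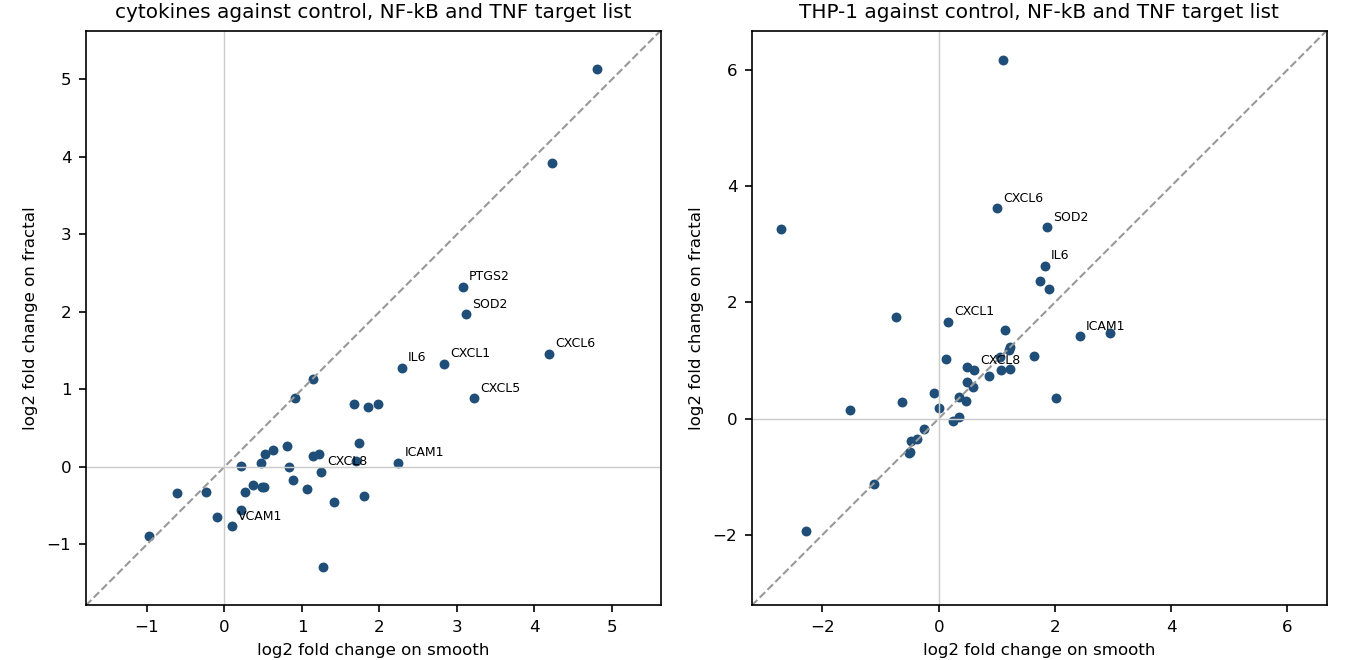
Log2 fold change against control of each of 40 NF-kB and TNF target genes on smooth (horizontal axis) and fractal (vertical axis), for cytokines on the left and THP-1 on the right. Each point is a gene and the dashed line marks equal responses. With cytokines the median is 1.15 on smooth and 0.06 on fractal, and with THP-1 it is 0.49 and 0.84.

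The THP-1 groups ask how podocytes respond to macrophages. Summed monocyte and macrophage markers stood at 102 CPM on smooth and 49.0 CPM on fractal in these libraries, against 8.0 and 8.70 CPM in the controls, and the counts do not show which cell type a transcript came from. On smooth topography 17 of 19 monocyte and macrophage markers rose and 1, SRGN, fell (18 and 1 adjusted over the list alone), with a median of 4.23 (4.17 with genes at 0 set to the floor). ITGB2, the beta 2 integrin of leukocytes, went from 0.20 ± 0.14 to 22.2 ± 0.99 CPM, and LAPTM5 from 0.13 ± 0.06 to 14 ± 0.38 CPM. CHI3L1, a secreted chitinase-like protein gene, had no count in smooth controls and was at least 636-fold higher. A2M, LCP1 and LPL, also without a count there, were at least 152-fold, 151-fold and 112-fold higher. IL33 rose by 5.38 ± 0.28. FGB (-8.04 ± 0.67), POSTN, the matrix protein periostin (1002 ± 10 to 43.0 ± 5.8 CPM, -4.54 ± 0.13), DKK1, a Wnt antagonist (-3.99 ± 0.25), MEST (-3.85 ± 0.29), CHAC1, which degrades glutathione (-3.68 ± 0.47), and EPPK1 (-3.62 ± 0.39) fell most.

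Type I interferon response genes rose in 28 of 32 cases (STAT2 by 0.94 ± 0.09), MHC class I genes in 16 of 17 (HLA-B by 1.46 ± 0.10) and complement genes in 8 of 14, with 1 falling (C3 by 2.24 ± 0.13), on smooth topography with THP-1. In the NF-kB and TNF target list 24 of 40 rose and 7 fell (24 and 8 over the list alone), with ICAM1 at 2.43 ± 0.09, TRAF1 at 2.95 ± 0.13, IL6 at 1.82 ± 0.09 and the chemokine CXCL2 at -1.53 ± 0.18. Endothelial markers rose in 5 of 9 cases, with PECAM1, which leukocytes express too, at 3.75 ± 0.42. Their call held without the libraries that stood apart, but not with an estimated correlation as well (adjusted p = 0.109). Ribosomal protein genes fell in 33 of 37 cases (36 over the list alone), unfolded protein and integrated stress response genes in 19 of 26 (the cystine transporter SLC7A11 by -2.42 ± 0.20) and YAP and TAZ target genes in 13 of 21, with 2 rising (ANKRD1 by -2.63 ± 0.17). Fibrillar collagen and stromal matrix genes fell in 17 of 27 cases and rose in 5 (18 and 7 over the list alone), and mesangial and smooth muscle markers fell in 5 of 10. Cell cycle genes fell in 22 of 35 cases, or 23 with 1 rising over the list alone (adjusted p = 0.122 with an estimated correlation). TNF rose (0.13 ± 0.06 to 1.54 ± 0.75 CPM) and VCAM1 fell (-0.48 ± 0.09).

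On fractal topography THP-1 lowered each of the 35 cell cycle genes, with a median of -2.56, and TOP2A went from 346 ± 1.0 to 50.9 ± 1.5 CPM. Complement genes rose in 9 of 14 cases and fell in 1 (10 and 1 over the list alone), with a median of 1.86 and C3 going from 40.7 ± 0.96 to 1265 ± 37 CPM. Of NF-kB and TNF target genes 25 of 40 rose and 5 fell (25 and 6 over the list alone), with a median of 0.84 (0.78 with genes at 0 set to the floor), SOD2 at 3.29 ± 0.12, IL6 at 2.63 ± 0.09, CXCL6 at 3.62 ± 0.14, CCL2 at 2.23 ± 0.30, ICAM1 at 1.41 ± 0.09 and the pentraxin PTX3 at -1.94 ± 0.23. Monocyte and macrophage markers rose in 16 of 19 cases and fell in 1 (17 and 2 over the list alone), with a median of 4.36 (3.00 with genes at 0 set to the floor). Type I interferon response genes rose in 19 of 32 cases (21 over the list alone) and MHC class I genes in 12 of 17 (14 over the list alone), with 1 gene falling in each list. Of 15 IL-6 and STAT3 response genes 9 rose and 2 fell, and of 24 p53 target genes 15 rose and 3 fell, with TP53INP1 at 1.87 ± 0.15 and CDKN1A at 0.88 ± 0.08. YAP and TAZ target genes fell in 14 of 21 cases (15 over the list alone) and rose in 3, with ANKRD1 at -5.24 ± 0.21, mesangial and smooth muscle markers fell in 7 of 10 and rose in 1, and TGF-beta target genes fell in 9 of 26 (10 over the list alone) and rose in 4. Without the libraries that stood apart the IL-6 and STAT3, p53 and TGF-beta lists kept their calls with the preset correlation and missed the threshold with an estimated one (adjusted p = 0.0516, 0.0721 and 0.0721 with an estimated correlation). Ribosomal protein genes fell in 29 of 37 cases (adjusted p = 0.16 with an estimated correlation).

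Genes with no count in fractal controls included CHRNA1, a subunit of the nicotinic acetylcholine receptor, the chemokine receptor gene CXCR4, MAP1LC3C and the potassium channel gene KCND2. With THP-1 they were at least 173-fold, 144-fold, 124-fold and 122-fold higher. SAA2, CHI3L1 and CYP1A1 rose from 1, 2 and 1 counts over the control group to 10.5 ± 2.5, 17.6 ± 5.1 and 6.05 ± 0.95 CPM, and BDKRB2, the bradykinin B2 receptor gene, rose by 8.04 ± 0.35. FGG had no count in the fractal THP-1 libraries and was at least 129-fold lower. FGB (-8.58 ± 0.52), DKK1 (-6.18 ± 0.30), the carboxypeptidase gene CPA4 (-5.90 ± 0.24), FGA (-5.76 ± 0.57), MEST (-4.49 ± 0.30) and CCBE1 (-4.22 ± 0.16) fell. By edgeR's quasi-likelihood test 5655 genes changed with THP-1 on smooth (2794 higher, 2861 lower) and 8149 on fractal (4035 higher, 4114 lower). Which direction held more genes depended on the scaling: with upper-quartile factors the splits were 3027 to 2633 and 4710 to 3535, and with RLE factors 2840 to 2813 and 4205 to 3972.

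Between the topographies under THP-1, the 35 cell cycle genes were all lower on fractal, with a median of -1.91. TOP2A (ENSG00000131747) stood at 50.9 ± 1.5 CPM against 186 ± 21 on smooth, RRM2, a subunit of ribonucleotide reductase, at 6.92 ± 1.9 against 42.2 ± 5.1, and the transcription factor FOXM1 at 7.45 ± 2.8 against 45.7 ± 1.7. CENPM (-2.73 ± 0.33), SKA3 (-2.65 ± 0.24), CLSPN (-2.50 ± 0.20) and DDIAS (-2.49 ± 0.21), which act in chromosome segregation or the response to DNA damage, fell too. SERPINB2 (-3.12 ± 0.17) and ANKRD1 (-2.57 ± 0.23) were also lower. BDKRB2 (2.79 ± 0.22), the retinol dehydrogenase gene DHRS9 (2.75 ± 0.33), CSGALNACT1 (2.69 ± 0.28), KCND2 (2.48 ± 0.45), SAA1 (2.29 ± 0.23), CYTIP (2.20 ± 0.20), GALNT15 (2.18 ± 0.13) and CXCL6 (117 ± 3.8 to 520 ± 66 CPM, 2.15 ± 0.13) were higher.

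Complement genes were higher on fractal under THP-1 in 5 of 14 cases and lower in 1 (8 and 1 adjusted over the list alone), with C3 at 1.53 ± 0.12 and C1R at 1.35 ± 0.11. Of 15 IL-6 and STAT3 response genes 6 were higher and 2 lower (6 and 3 over the list alone), with CEBPD at 1.29 ± 0.13. Monocyte and macrophage markers were lower in 7 of 19 cases, with ITGB2 at -1.36 ± 0.23 and a median of -1.15. Without the libraries that stood apart the IL-6 and STAT3 list and the marker list (median -1.13) kept their calls with the preset correlation (adjusted p = 0.000768 and 0.015), and both missed the threshold with an estimated correlation (adjusted p = 0.159 for each). The NF-kB and TNF target list did not pass as a whole (12 higher, 9 lower, median -0.07, mean 0.14, adjusted p = 0.315). CXCL8 (1378 ± 25 and 1255 ± 74 CPM, adjusted p = 0.268) and CCL2 (131 ± 3.5 and 79.6 ± 33 CPM, adjusted p = 0.092) did not differ by the test. IL6 was higher (0.34 ± 0.09), though in a fit to these 6 libraries alone it missed the threshold (adjusted p = 0.054). Type I interferon response genes were lower in 13 of 32 cases and higher in 1, or 17 and 2 over the list alone (adjusted p = 0.072 with an estimated correlation). Integrin and focal adhesion genes were lower in 11 of 32 and higher in 1, or 13 and 2 over the list alone (adjusted p = 0.438 with an estimated correlation). edgeR's quasi-likelihood test called 3220 genes, 1330 higher and 1890 lower, and 1401 in a fit to these 6 libraries alone. Under upper-quartile scaling it called 1625 higher and 1626 lower.

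**Figure D4:**
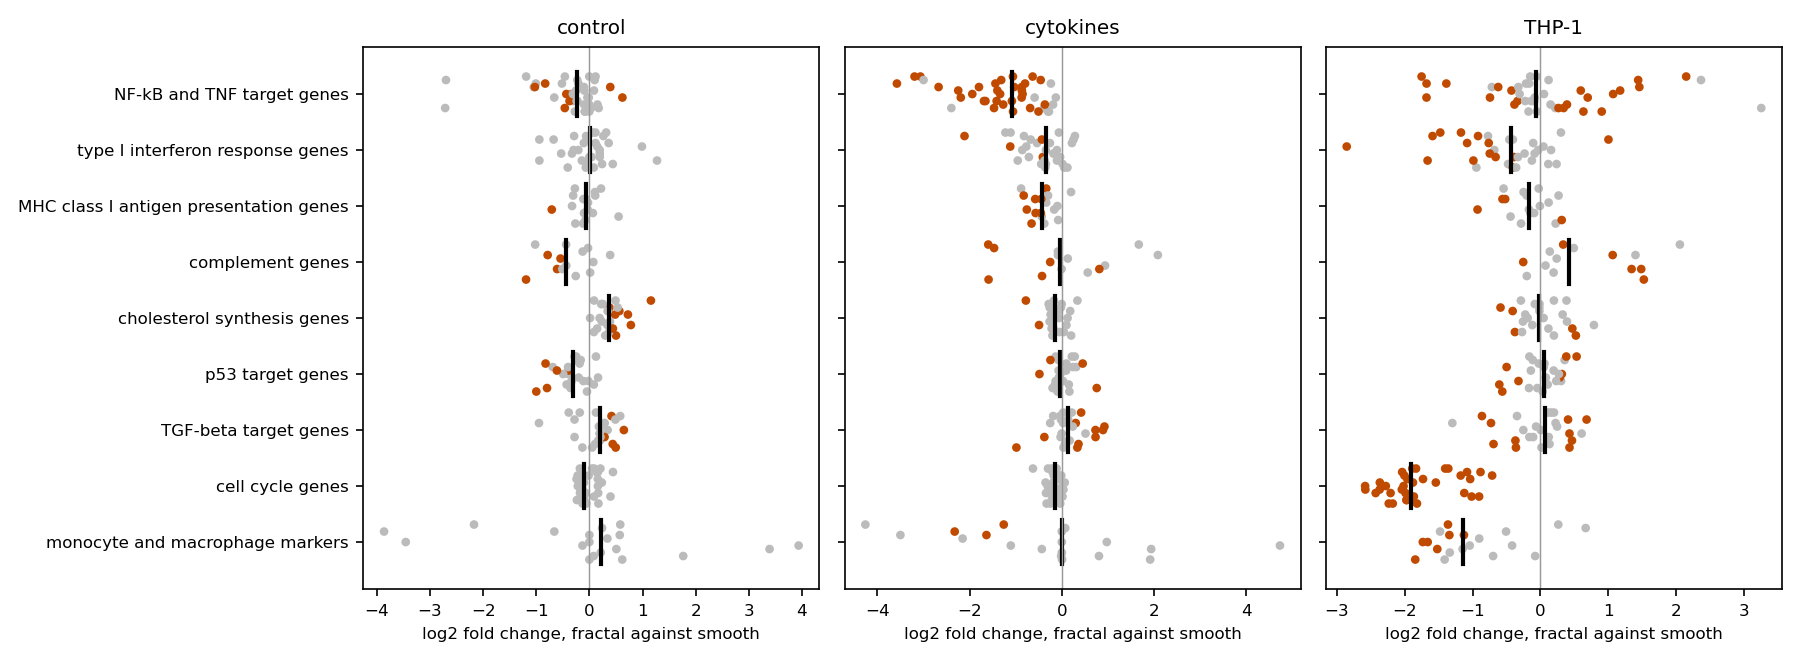
Log2 fold change, fractal against smooth, of each member of 9 gene lists under control, cytokines and THP-1. Each point is a gene, orange where it passed edgeR's test and grey where it did not, and the black bar is the list's median, which is -1.07 for NF-kB and TNF target genes under cytokines and -1.91 for cell cycle genes under THP-1.

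In the interaction of topography and THP-1, the 35 cell cycle genes all had a more negative response on fractal, with a median difference of -1.78 (TOP2A -1.76 ± 0.13, RRM2 -2.75 ± 0.20). Complement genes had a more positive response in 6 of 14 cases and a more negative one in 1 (8 and 1 over the list alone), with C3 at 2.72 ± 0.18. In the NF-kB and TNF target list 8 of 40 had a more positive response and 3 a more negative one (11 and 5 over the list alone), with a median of 0.085 and a mean of 0.51. Without the libraries that stood apart the list, with a median of 0.14, kept its call with the preset correlation (adjusted p = 0.000718) and missed the threshold with an estimated correlation (adjusted p = 0.0645). CXCL6 (2.61 ± 0.18), CXCL1 (1.51 ± 0.12), SOD2 (1.43 ± 0.15) and IL6 (0.81 ± 0.13) were above 0, and TRAF1 (-1.47 ± 0.18), ICAM1 (-1.01 ± 0.13) and CD83 (-1.67 ± 0.39) below. Of 24 p53 target genes 7 differed upwards and 1 downwards (7 and 2 over the list alone), with CDKN1A at 0.80 ± 0.11. SAA1 (4.23 ± 0.78), BDKRB2 (4.22 ± 0.66), CHRD (3.81 ± 0.37), the transcription factor EHF (3.70 ± 0.55), TMPRSS2 (3.60 ± 0.68) and CLSTN2 (3.58 ± 0.44) had a more positive response, though SAA1 missed the threshold with limma-voom (adjusted p = 0.065). CENPM (-3.05 ± 0.42), NRGN (-2.97 ± 0.30), CPA4 (-2.77 ± 0.32), SERPINB2 (-2.66 ± 0.25), ANKRD1 (-2.60 ± 0.27), CLSPN (-2.59 ± 0.26) and GINS2 (-2.47 ± 0.28) differed the other way. For the macrophage markers the interaction did not pass (1 of 19 differed, adjusted p = 0.267).

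The test of this interaction called 2134 genes, 863 with a more positive and 1271 with a more negative difference. The count was 3258 without fractal THP-1 replicate 3 and 3652 without the libraries that stood apart. Under upper-quartile scaling the split was 1077 to 1014. CXCL8 had a difference of 0.24 ± 0.11 (adjusted p = 0.184) that passed without fractal THP-1 replicate 3 (0.033). Over the 8980 genes that responded to THP-1 on average, the response was larger on fractal. The median signed difference was 0.225 on the log2 scale (exact permutation test, two-sided, p = 0.005, the smallest that 400 relabellings can give). Median responses were 0.466 on smooth and 0.707 on fractal, and 28.6% of these genes had the larger response on smooth. Summed macrophage markers went the other way, being lower on fractal.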

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

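The run without the pair of libraries that stood apart, the splits of the libraries, the test of weaker exposure and the test of opposite effects were chosen after the results they bear on were seen. Results are listed here where the effect of 1 factor differed between the levels of the other by a test of the difference itself, or, in the last paragraph, where genes were picked because 2 effects of topography ran in opposite directions.

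The NF-kB and TNF target genes responded less to cytokines on fractal topography, with a median difference of -0.85. If weaker exposure to both cytokines shrank every response in proportion, a loss as large as the list's would give a median signed difference of about -0.32. The tables argue against such an even loss: the difference over responsive genes was -0.00080, and the median over IL-6 and STAT3 response genes was 0.09. A weaker exposure whose effect is uneven over genes stays open. Leaving out each of 12 libraries kept the list's median between -0.82 and -0.88, and the other scalings gave -0.84 and -0.82, which argues against a single library or the scaling. A weaker exposure to TNF-α alone stays open, because no list separates it from a change within the cells. An effect of topography on the response of these genes may remain as a hypothesis, found and tested on the same data.

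Topography changed the response to cytokines in 436 genes and the response to THP-1 in 2134 genes. Of 100 splits drawn for each interaction, 1, the real one, gave as many genes, the highest other counts being 209 and 1229. That share does not exclude chance. A split that mixes topographies carries their difference in its spread, which lowers its count, and the libraries of a group may share a culture. The response to THP-1 over all responsive genes was larger on fractal by a median of 0.225. Under cytokines the median differences were -0.30 for type I interferon response genes, -0.31 for MHC class I antigen presentation genes, -0.42 for cholesterol synthesis genes, 0.25 for p53 target genes and 0.28 for immediate early genes. Under THP-1 they were 0.085 for NF-kB and TNF target genes, 0.78 for complement genes, -1.78 for cell cycle genes and 0.41 for p53 target genes. Both interactions subtract the same difference between controls, which had a median of -0.31 for p53 target genes. That list did not pass camera between topographies under cytokines or THP-1, so its interaction results are not separate evidence. For cholesterol synthesis genes the median was 0.37 between controls and -0.15 under cytokines (camera with an estimated correlation, adjusted p = 0.219). Without the pair of libraries that stood apart, the interferon list under cytokines and the NF-kB list under THP-1 missed the threshold with an estimated correlation (adjusted p = 0.0751 and 0.0645).

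Several genes had opposite effects of topography under cytokines and under THP-1. The effect under THP-1 minus that under cytokines was 5.34 for CXCL6, 5.15 for TMPRSS2, 4.45 for IQCD, 4.39 for SAA1, 3.46 for CSGALNACT1 and -3.20 for ANKRD1. That difference is not among the 9 comparisons, and the genes were picked for opposite effects, each past the threshold in both, so a test of the difference on them adds no evidence. CXCL6 had a topography effect of -3.19 with cytokines and 2.15 with THP-1.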

How the results depend on the processing

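The run without smooth cytokines replicate 2 and fractal THP-1 replicate 3 and the splits of the libraries were chosen after the results were seen. Counts of genes, in the order fractal against smooth in control, cytokines and THP-1, cytokines on smooth and fractal, THP-1 on smooth and fractal, and the interactions with cytokines and THP-1, were 74, 195, 677, 1037, 994, 1459, 3047, 174 and 706 with an absolute log2 fold change of at least 1, the cause being the added threshold. DESeq2 gave 513 for the controls and 688 for the cytokines interaction. A fit to the groups compared gave 2743 for the controls, 1401 for THP-1 and 984 for the cytokines interaction. Without the pair of libraries that stood apart, the counts were 1199 and 1569 for fractal against smooth in control and cytokines, and 1472 and 3652 for the interactions. For these the cause was not tested.

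Leaving out each library in turn gave 130 to 153, 472 to 743 and 2348 to 3848 genes for fractal against smooth, 3260 to 4032 and 3157 to 3584 for cytokines, 4624 to 4906 and 7187 to 8523 for THP-1, and 270 to 531 and 1615 to 3258 for the interactions. The response size ran from -0.0411 to 0.0244 with cytokines, and was 0.00052 with a prior count of 0.5; it ran from 0.207 to 0.262 with THP-1, past its threshold each time. The other alternatives kept every count within 1.5 times. Replicate numbers did not pair the libraries (correlations between residuals of -0.067 to 0.064); with the number as a block the counts were 283, 694, 3114, 4063, 4075, 5565, 8059, 416 and 2086, and labels swapped within the block gave p of 1 and 0.03125, the smallest that 64 relabellings can give. For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05; the real counts stood against at most 1 in any other split.

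Of 135 list calls, 65 were lost with an estimated correlation, 9 with fry, 2 with the block, 8 without the pair of libraries and 23 without some single library, and none reversed. Of 249 results for named genes, 5 were lost with limma-voom, 5 with a fit to the groups compared and 5 without some single library, and none reversed. Depth limits low genes: the floor of a group lay between 0.0535 and 0.0662 CPM.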

Other observations

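The run without the pair of libraries that stood apart, the tests of GC content, length and labels for fractal THP-1 replicate 3 and the tests on macrophage RNA were chosen after the results they bear on were seen, and no other test in this part was. Genes of the podocyte itself moved both ways. Of 25 measured podocyte genes, 12 rose and 5 fell with cytokines on smooth topography (12 and 6 adjusted over the list alone) and 9 rose and 4 fell on fractal (9 and 5 over the list alone), and the list passed camera in neither (adjusted p = 0.417 and 0.0793). On fractal it passed without the pair of libraries (adjusted p = 0.0405), though not with an estimated correlation as well (adjusted p = 0.218). With THP-1, 9 rose and 6 fell on smooth and 11 rose and 8 fell on fractal (adjusted p = 0.475 and 0.119). SYNPO, which encodes the actin-bundling protein synaptopodin, rose with cytokines on smooth (66.6 ± 3.2 to 106 ± 14 CPM) and on fractal (69.1 ± 2.5 to 114 ± 8.9 CPM). PODXL, the sialomucin podocalyxin, fell with THP-1 on fractal (10.1 ± 1.1 to 2.55 ± 0.72 CPM).

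Monocyte and macrophage markers appeared in the THP-1 libraries at a lower level on fractal topography. The median ratio was 0.378, from 0.30 to 0.574. It covers the 11 markers with at least 1 CPM in smooth THP-1 and at most 0.3 CPM outside THP-1. The interaction over the list did not pass camera (adjusted p = 0.267). That interaction rests on folds against controls, where those 11 markers had few or no counts, so it cannot decide on the direct ratio. RNA of the added macrophages in the lysates may be the source: the SD of the markers' log2 ratios was 0.286, below the median of 0.953 in random sets drawn from 60 other genes that met the same limits (median ratio 0.44), and with the minimum set on fractal THP-1 instead the markers' median was 0.385 over 6 markers and that of 43 other genes 1.39. Of the markers, ITGB2 had 22.2 CPM on smooth and 8.61 CPM on fractal, and LAPTM5 14 and 4.78 CPM, with TMM scaling, which the ratios do not use. Whether that RNA also carries the rise of NF-kB and TNF target genes with THP-1 stays open. Over the 24 members that rose on smooth, the gain on fractal was 0.752 of that on smooth at the median. This lay between the markers' ratio under either minimum and 1. The members were mixed, with 11 ratios above 0.8 and 4 within 0.2 of the markers' 0.378. Picking members by their rise on smooth tends to lower the ratio. Of these 24 members, 4 rose more on fractal by the interaction test. Macrophage RNA of the same profile on both topographies would not give this alone. These 4 members were picked by that test, so they add no evidence beyond it. A profile that differs between topographies stays open.

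Fractal THP-1 replicate 3 had counts for 17934 genes and a low share of mitochondrial counts. Lower depth is argued against, since companions thinned to its total still had 21918 genes with a count (SD 129 over draws). Mitochondrially encoded mRNAs differed from nuclear genes of like GC content and length by a median log2 gap of -3.29 (SD of those genes 0.70), which argues against GC content or length for these mRNAs. Across 9608 nuclear genes the deviation went with GC content (Spearman 0.382) and length (-0.163), but companions thinned along that trend still had 21979 genes with a count (SD 153), which argues against it as the whole source of the missing genes. Against each other group, most called genes placed the library nearer to its companions. The share was 62.7% against smooth THP-1 and from 69.5% to 75.2% against the rest. This argues against a wrong label, least strongly for smooth THP-1. Low input or RNA quality was not tested, nor was any biological explanation.

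The list of genes controlled by SRF and genes of the actin cytoskeleton passed camera downwards with both treatments on both topographies, and each of these calls was lost with an estimated correlation. With cytokines 12 of 26 fell on smooth (14 over the list alone; adjusted p = 0.259 with an estimated correlation) and 10 fell and 1 rose on fractal (adjusted p = 0.546). With THP-1, 14 fell and 2 rose on smooth (16 and 2 over the list alone; adjusted p = 0.158), and 16 fell on fractal (17 over the list alone; adjusted p = 0.205). Neither interaction passed camera (adjusted p = 0.146 and 0.225).

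Nuclear genes of oxidative phosphorylation also passed camera downwards in all 4 of these comparisons, though not with an estimated correlation. With cytokines 5 of 35 fell and 1 rose on smooth (adjusted p = 0.245 with an estimated correlation), and 12 fell on fractal (13 over the list alone; adjusted p = 0.108). The call on smooth was lost without smooth cytokines replicate 1 (adjusted p = 0.0529). With THP-1, 18 fell on smooth (19, with 1 rising, over the list alone; adjusted p = 0.0793) and 21 on fractal (22 over the list alone; adjusted p = 0.0887). Neither interaction passed camera (adjusted p = 0.288 and 0.089), though that with THP-1 did without the pair of libraries (adjusted p = 0.00551, or 0.194 with an estimated correlation). In that run the calls with THP-1 on smooth and fractal and with cytokines on fractal held with an estimated correlation too (adjusted p = 0.0282, 0.0176 and 0.0399).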
